A study of Arabidopsis thaliana with 6 samples.

How the data were processed

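Gene expression was measured with Affymetrix arrays in whole Arabidopsis thaliana seedlings aged 14 days, with 3 arrays of the pkl-1 mutant and 3 of the Col-0 wild type. The labels call the 3 samples of each genotype biological replicates. Per the labels' protocols, seedlings grew on Murashige and Skoog agar under continuous light, total RNA was extracted with a column kit, and biotin-labelled RNA was hybridised by the manufacturer's standard procedure. The deposited values are log2 signals per probe set, made with GCRMA per the submitters' processing notes. GCRMA subtracts a background that depends on probe sequence, normalizes the arrays to one another and summarises the probes of a set. Its version, and the genome build and annotation behind the array, are not given in the sources used here. That the scale is log2 was read from the values, which ran from 0.597 to 13.7 with array medians between 5.03 and 5.13. Background correction of this kind leaves dim probe sets piled up at low values with little spread, so that fold changes that start or end near that level depend on the correction.

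The table held 22810 probe sets. The 64 control probe sets were left out of the tests, and the other 22746 were tested without a filter on signal. A table of the platform's annotation paired 13513 probe sets with 1 gene and 503 with several, and 8730 were unnamed here. Symbols were updated through the gene table of the TAIR10.1 assembly, in which 13436 of the probe sets with 1 gene had a locus. No probe set with several genes was given a name, and no coordinates are printed, since the build is unnamed. The probe set of PKL was among those unnamed here, so that the level of the mutated gene, planned as the first result, is not reported and the labels could not be checked against it.

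The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-dependent prior), 2-sided, as pkl-1 minus wild type on the log2 values, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. Probe sets past the threshold are called changed, and a second count took those with a log2 change of at least 1, which is 2-fold. Errors of log2 changes are the moderated standard errors of that fit. No further normalization was applied. Arrays have no read depth, and their number, 3 per genotype, limits the precision; the median standard error of a log2 change was 0.156. On simulated data with the real means and spreads, in which 200 of 22746 probe sets, all with a mean above 2.82 log2 units, were changed, the fit called 54% of those changed 2-fold and 86% of those changed 4-fold, and 5 unchanged probe sets, which were 3.45% of its calls.

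Before the data were examined, 25 gene lists with 463 members were fixed for tissues, pathways and chromatin complexes. A member was used if a probe set paired with that gene alone measured it, with the probe set of highest mean standing for the gene; 11 members whose symbol the gene table did not give for the locus were left out. This left 70 members. No member of the list of PRC2 subunits was measured by a named probe set, 14 lists had 1 or 2 members, and the 10 lists with at least 3 were tested with limma's camera at a preset correlation of 0.01, with the estimated correlation and fry beside it. The minimum of 3 members was set after the coverage of the lists was known. Calls adjusted over a list alone correct for the measured members of that list only, and not over the lists. In a list of 1 measured member they leave the p unadjusted, and in a list of 2 they correct for 2 tests. In 100 simulated draws with noise independent between genes, camera called the photosynthesis list of 6 members in 100 when it was shifted by -0.2 log2 units, and called any list in 6 without a shift; real genes are correlated, which this leaves out.

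The genes named in the results were set by a rule, except AGL19, FD and THI2.1, which complete lists of 2 or 3, and EXPA8 and XTH33, which had the largest changes of their list; these were named after their values were seen. The rule was also fixed before the data were examined. It takes PKL, the 12 largest rises and 12 largest falls among changed probe sets that name 1 gene and whose pkl-1 arrays all lay beyond all wild-type arrays, up to 2 rises and 2 falls among the changed members of each list, any member of the lists of embryo regulators and PRC2 subunits, and at most the 2 brightest members of a list without a change. The alternatives tried were other moderation of the variances, leaving out probe sets with a mean under 2.82 log2 units, quantile normalization, centring on array medians, array weights, the replicate number as a block, each array left out in turn, an adjusted p under 0.01, and a test against a 1.2-fold change. Families of genes whose symbols begin with the same letters were tested as an addition chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.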

Results

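PICKLE (PKL) encodes a chromatin remodelling ATPase of the CHD3 class, and pkl-1 is a mutant allele of it. Whole seedlings of pkl-1 and of the Col-0 wild type were profiled at 14 days, with 3 arrays each, to find the genes whose transcript levels differ between them. Array medians lay between 5.03 and 5.13 log2 units. Correlations of the levels across probe sets were 0.985 to 0.9937 within a genotype and 0.9751 to 0.9892 between genotypes. The median standard deviation of a probe set was 0.163 log2 units in pkl-1 and 0.171 in wild type (n = 3 each).

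In pkl-1, 540 of 22746 probe sets were changed, 242 higher and 298 lower. Of these, 119 were at least 2-fold higher and 184 at least 2-fold lower. Rises had a median of 0.99 log2 units and falls a median of -1.14. A single gene name was attached to 271 of the changed probe sets, covering 117 genes that rose and 153 that fell, while 12 changed probe sets matched several genes and 257 were unnamed here. The strongest rise of all, 7.44 ± 0.17 log2 units (174-fold), belonged to a probe set that matches 2 genes and is therefore not named. Its wild-type level was 1.58 ± 0.12 (SD, n = 3), near the lower end of the signal, so that its fold depends on the background GCRMA estimated.

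**Figure D1:**
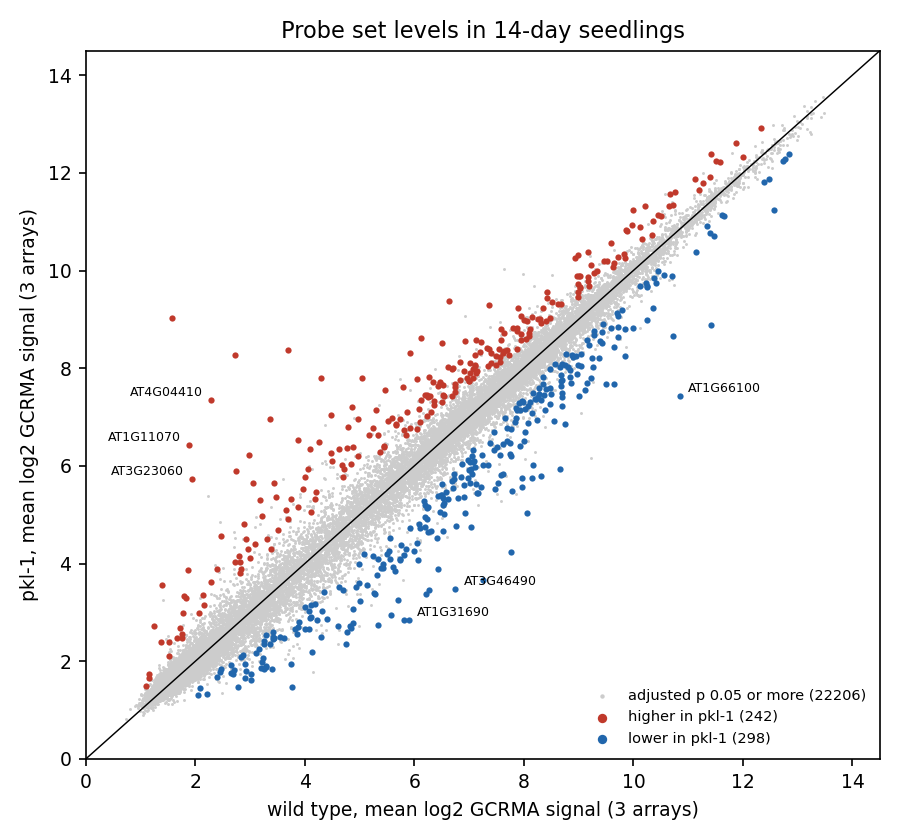
Mean log2 GCRMA signal of each probe set in wild type (horizontal axis, 3 arrays) and pkl-1 (vertical axis, 3 arrays), with 242 probe sets higher in pkl-1 in red, 298 lower in blue and the others in grey. The line marks equal levels, and the 3 largest rises and 3 largest falls with a gene name are labelled.

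The 3 largest rises with a gene name began at wild-type levels near the lower end of the array's signal. AT4G04410, a pseudogene in the gene table, rose from 2.28 ± 0.23 to 7.35 ± 0.15 (SD, n = 3 each), a 33.6-fold difference (limma adjusted p = 8.20e-05). AT1G11070 rose by 4.55 ± 0.32 log2 units (SE) and AT3G23060 by 3.79 ± 0.22, with wild-type means of 1.88 and 1.94. AT3G23060 is known as BMI1C, a RING-finger protein related to subunits of the Polycomb complex PRC1; its list did not count it, since the gene table gives no symbol for it. Because these folds start near background, they depend on how GCRMA estimated it.

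The other large rises began at higher wild-type levels. ICL, isocitrate lyase of the glyoxylate cycle that converts stored lipid to sugar in germinating seeds, rose from 6.63 ± 1.03 to 9.37 ± 0.30 (SD, n = 3 each), which is 6.68-fold (limma adjusted p = 0.0260); this call was lost without any 1 pkl-1 array or without wild type replicate 3 (adjusted p 0.0575 to 0.132) and with a robust prior (0.0795). QQS, a gene without relatives in other species that affects starch content, rose by 2.76 ± 0.30 log2 units. AT4G33720, of the family of pathogenesis-related protein 1, rose by 2.56 ± 0.22, and the DnaJ-domain gene AT5G53150 by 2.40 ± 0.16. The jacalin-type lectin JAL23 rose by 2.34 ± 0.27 and COR27, which responds to cold and light, by 2.25 ± 0.24. AT1G07050, which encodes a CCT-motif protein, rose by 3.24 ± 0.52, AT5G26270 by 2.66 ± 0.25 and AT1G78450 by 2.60 ± 0.37; the wild-type means of AT1G07050 and AT1G78450 were low too, at 2.97 ± 0.72 and 3.06 ± 0.37 (SD, n = 3 each). Both lost their calls without pkl-1 replicate 1, pkl-1 replicate 2 or wild type replicate 2 (limma adjusted p up to 0.118 and 0.0829), and AT1G07050 also without wild type replicate 3 (0.0558).

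The largest named fall was that of the thionin gene AT1G66100, which encodes a small antimicrobial peptide. Its level was 10.84 ± 0.29 in wild type and 7.43 ± 0.21 in pkl-1 (SD, n = 3 each), a 10.6-fold difference (limma adjusted p = 1.74e-04). The chitinase-family gene AT2G43590 fell by 2.73 ± 0.14 log2 units, and the lipid-transfer protein gene AT5G48490 fell by 2.53 ± 0.25. The copper amine oxidase gene AT1G31690 fell by 3.06 ± 0.27 and AT5G48570, the heat-inducible FKBP-type immunophilin ROF2, fell by 2.63 ± 0.31; their pkl-1 levels of 2.84 and 2.94 were low, so that these sizes depend on the background estimate too. The beta-expansin gene EXPB1, whose product loosens cell walls, fell by 2.29 ± 0.37. The other falls, apart from that of AGL24 given below, were -3.27 ± 0.26 log2 units for AT3G46490, -3.03 ± 0.57 for AT2G32160, -2.83 ± 0.46 for AT5G37990, -2.41 ± 0.22 for AT3G22060 and -2.30 ± 0.25 for AT3G47295. AT3G46490 and AT5G37990 fell to fairly low pkl-1 levels of 3.48 ± 0.28 and 3.38 ± 0.86 (SD, n = 3 each). The background estimate may enter the sizes of these falls too. The call of AT2G32160 was lost without any 1 array except pkl-1 replicate 2 (adjusted p 0.0739 to 0.146), without a trend (0.0611), with a robust prior (0.105) and with array weights (0.0530). AT5G37990 lost its call without any 1 array except pkl-1 replicate 3 (0.0536 to 0.0742), EXPB1 without either replicate 2 or pkl-1 replicate 3 (0.0793 to 0.114) and AT5G48570 without pkl-1 replicate 2 (0.0539).

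**Figure D2:**
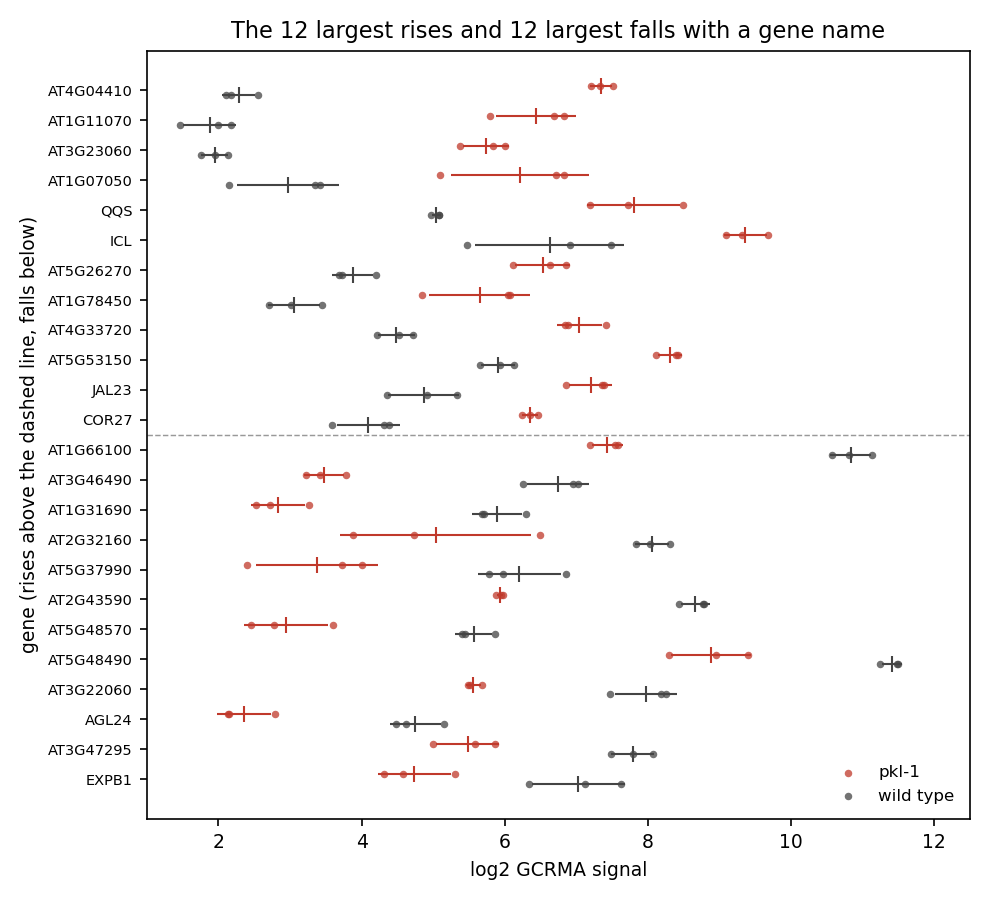
Log2 GCRMA signal (horizontal axis) of the 12 largest rises and 12 largest falls with a gene name (vertical axis), with pkl-1 in red and wild type in grey. Points are single arrays, vertical ticks the means of 3 arrays and bars 1 SD. In each gene the 3 pkl-1 arrays lie to one side of the 3 wild-type arrays, which the rule that chose the genes required.

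The flowering-time list was lower in pkl-1 as a group (camera adjusted p = 0.0220), with an adjusted p of 0.312 under an estimated correlation. That estimate was -0.107, lower than the preset 0.01, so that a higher correlation did not end the call. Of its 16 members 3 were measured by named probe sets. AGL24, a MADS-box promoter of flowering, fell from 4.75 ± 0.35 to 2.35 ± 0.37 (SD, n = 3 each; limma adjusted p = 0.00683) and was the only one to pass over all probe sets, while 2 passed when adjusted over the list alone. Its pkl-1 level lay near the lower end of the signal, so that the size of the fall depends on the background estimate. AGL19 was at -0.64 ± 0.21, with low levels of 1.84 in pkl-1 and 2.47 in wild type, and FD was at -0.06 ± 0.13. Of the related list of phase-change genes, SNZ and SMZ were measured, both AP2-type repressors of flowering. Neither passed over all probe sets, with log2 changes of -1.58 ± 0.44 and 0.59 ± 0.24, and both passed when adjusted over the list alone. SNZ did pass over all probe sets with the replicate number as a block (limma adjusted p = 0.0169), and SMZ did not (0.117).

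Nuclear-encoded photosynthesis genes were also lower as a group (camera adjusted p = 0.0220). Under an estimated correlation, here 0.0596, the camera adjusted p was again 0.312. All 6 measured of 37 members had negative changes, with a median of -0.19 log2 units. LHCB4.2, an antenna protein of photosystem II, fell by 0.50 ± 0.09 and alone passed over all probe sets; 4 passed when adjusted over the list alone.

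In the cold, drought and abscisic acid list, COR15A, a chloroplast protein that protects membranes during freezing, rose by 0.78 ± 0.16 log2 units, and the other 3 measured members did not pass. All 4 changes were positive (camera adjusted p = 0.0777), and 2 passed when adjusted over the list alone. In the list of jasmonate and ethylene defence genes, the defensin gene PDF1.2 fell by 1.56 ± 0.20. The other measured member, THI2.1, went the other way at 0.46 ± 0.19 without passing over all probe sets, and both passed when adjusted over the list alone. SAG29, a sugar transporter gene of the SWEET family that marks senescence, fell by 1.80 ± 0.25, to a level of 2.49 near the lower end of the signal, and was the only one of 2 measured senescence genes to pass, also when adjusted over the list alone. Among 7 expansins and xyloglucan-modifying enzymes XTH19 fell by 1.14 ± 0.22 and 6 did not pass, while 2 passed when adjusted over the list alone, XTH19 and EXPA8. EXPA8 had a larger difference, -3.07 ± 0.90, with levels of 6.16 ± 1.75 in pkl-1 and 9.23 ± 1.29 in wild type (SD, n = 3 each; limma adjusted p = 0.153). XTH33 was at 2.14 ± 1.11 (limma adjusted p = 0.432), and the other 6 changes were negative (camera adjusted p = 0.272). In pkl-1 and wild type alike, replicate 3 was the lowest array for EXPA8 (4.23 and 7.74) and the highest for XTH33 (8.05 and 5.13). Whether the numbers pair the arrays is open, and if they do, the errors given for these genes may be too large.

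The embryo programme was covered thinly. Of 15 embryo identity regulators only BBM and EEL were measured by named probe sets; neither passed, with log2 changes of -0.17 ± 0.15 and -0.60 ± 0.22. All 4 measured seed storage, oil body and late embryogenesis genes failed the test (camera adjusted p = 0.727), among them OLEO3 at 0.12 ± 0.21 and M10 at 0.29 ± 0.12, with levels near 2 log2 units in both genotypes. None of the 3 measured endosperm genes passed (camera adjusted p = 0.739), with AGL62 at -0.13 ± 0.15 and IKU2 at 0.10 ± 0.15. For these 3 lists the count adjusted over the list alone was also 0.

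Hormone lists had no member that passed over all probe sets. All 4 measured gibberellin genes had positive changes (camera adjusted p = 0.190, fry adjusted p = 0.0129), with the receptor gene GID1A at 0.55 ± 0.18 and SLY1 at 0.13 ± 0.12. The 9 auxin genes went both ways (camera adjusted p = 0.739), with GH3.3 at 0.36 ± 0.12 and GH3.5, listed as WES1, at 0.43 ± 0.36. In both lists 0 passed when adjusted over the list alone.

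The counted members of the remaining lists also did not pass over all probe sets. Flavonoid genes (3 measured, camera adjusted p = 0.352) included DFR at -0.09 ± 0.11 and UF3GT at -0.45 ± 0.21, and root markers (3 measured, camera adjusted p = 0.634) included PYK10 at 0.02 ± 0.09 and EXPA18 at -0.17 ± 0.25. Lists with 1 or 2 measured members were not tested as groups. Of chromatin genes, the Polycomb antagonist ULT1 was the only counted member of the PRC1 list, in which AT3G23060 was fixed and rose but was not counted. ULT1 was at 0.74 ± 0.42 and the remodelling ATPases CHR17 and INO80 at -0.07 ± 0.15 and -0.08 ± 0.15. With the replicate number as a block ULT1 passed (limma adjusted p = 0.00925), as did SNZ above and SAG101 and YAB3 below. The leaf polarity gene YAB3 was at 0.50 ± 0.15 and the stem-cell signal CLV3 at 0.02 ± 0.07, with YAB3 passing when adjusted over the list alone. The floral gene SPL was at 0.02 ± 0.09, the clock gene GI at 0.40 ± 0.23 and the defence gene SAG101 at 0.88 ± 0.32. SAG101 was the only measured member of its list, so that adjusting over the list alone left its limma p of 0.0236 unadjusted. FATB was at -0.08 ± 0.12 and FATA at -0.01 ± 0.16 among lipid genes, and AUR1 at -0.20 ± 0.12 and MCM7, listed as PRL, at -0.19 ± 0.13 among cell-cycle genes. Glucosinolate genes were BCAT4 at 0.06 ± 0.15 and UGT74B1 at 0.24 ± 0.21. Of the reference genes, GAPC2 was at -0.01 ± 0.05 and UBC21, listed as PEX4, at -0.35 ± 0.13, which passed when adjusted over the list alone.

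In all 540 changed probe sets the 3 pkl-1 arrays lay beyond the 3 wild-type arrays, which passing the test with 3 arrays each makes likely by itself. The same held in 21.0% of all probe sets, where chance gives 10%. The count of changed probe sets depended on every array, being 219, 123 and 229 without pkl-1 replicates 1, 2 and 3 and 303, 132 and 275 without wild type replicates 1, 2 and 3. The flowering-time call ended without pkl-1 replicate 1 (camera adjusted p = 0.0599) or wild type replicate 3 (0.0588), and the photosynthesis call without these (0.0599 and 0.0745), without pkl-1 replicate 3 (0.0632) or wild type replicate 1 (0.0650), and after quantile normalization (0.0733). Both calls also ended with the replicate number as a block (camera adjusted p = 0.0683 each). Of the changes named from the lists, XTH19 lost its call without any 1 of the 6 arrays (adjusted p up to 0.174), COR15A without any but wild type replicate 2 (up to 0.172), LHCB4.2 without pkl-1 replicate 2 or any wild-type array (up to 0.122), PDF1.2 without either replicate 2 (0.0566 and 0.0605) and SAG29 without pkl-1 replicate 2 (0.0744). Other settings, given below, also ended the calls of COR15A, XTH19 and LHCB4.2. All 5 kept their sign with 1 array left out, with log2 changes of -1.29 to -0.91 for XTH19 and 0.65 to 0.98 for COR15A.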

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

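The count of 540 changed probe sets stayed between 470 and 652 under other moderation of the variances, without the dimmest probe sets, under quantile normalization, centring on medians and array weights, and 44.4% to 44.9% were higher under both rescalings, against 44.8%. With 1 array left out this share ran from 40.0% to 53.7%, and rises outnumbered falls without pkl-1 replicate 3 (123 against 106) and without wild type replicate 2 (68 against 64). An adjusted p under 0.01 left 111 and a test against a 1.2-fold change 186, both stricter by construction. With 1 array left out, 123 to 303 probe sets were changed (57 to 142 higher, 64 to 165 lower, 105 to 221 at least 2-fold); 88 passed in all 6 such fits, and fewer arrays lower the power. Shifted gene lists numbered 0 to 3 with 1 array left out, 1 without the dimmest probe sets, where flowering time had under 3 members left, 1 under quantile normalization and 0 with an estimated correlation; for the last 2 the cause was not tested. Over the rescalings, filter, weights, block and left-out arrays, the camera adjusted p ran from 0.00894 to 0.0683 for flowering time and from 0.0192 to 0.0745 for photosynthesis. The moderation settings were varied in the fit of single probe sets only, and camera was run with the same setting throughout. The PKL alternatives were not run, as its probe set is unnamed here.

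With the replicate number as a block, 1518 probe sets were changed, 688 higher and 830 lower, 511 of them at least 2-fold, and 0 lists were shifted (adjusted p = 0.0683 for flowering time and photosynthesis alike); ULT1 (adjusted p = 0.00925), SNZ (0.0169), SAG101 (0.0225) and YAB3 (0.0449) passed only there. The cause was not tested. The labels state no batch shared by equal numbers. Deviations from the genotype means correlated across probe sets at 0.49 for both replicates 1, -0.02 for both replicates 2 and 0.58 for both replicates 3. Both replicates 2 correlated best with another number. The 3 deviations of a genotype sum to 0, so that with replicates 1 and 3 apart the value of replicates 2 cannot decide on a pairing. Whether the numbers pair the arrays is therefore open, and the main fit left them out. If they do, its errors are too large for genes that move with the number, such as ULT1. RNA quality may differ along this axis. From replicate 1 to 3, the 3' minus 5' signal of GAPDH and actin controls fell in both genotypes, but that of ubiquitin rose. These replicates were at opposite ends for no control in both genotypes, which leaves it open.

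Of 61 named genes, 29 were changed, and none of these changed sign in any alternative. Over 13 alternatives these 29 gave 377 values, of which 53 lost the call. Of the 24 largest changes 17 passed with each array left out; AT1G07050, ICL, AT1G78450, AT2G32160, AT5G37990, AT5G48570 and EXPB1 did not (adjusted p up to 0.146), nor did the 5 other changed genes, COR15A, XTH19, LHCB4.2, PDF1.2 and SAG29. Other settings ended the calls of AT2G32160, LHCB4.2 (adjusted p = 0.111), COR15A (0.0906) and XTH19 (0.0588) without a trend, ICL and AT2G32160 with a robust prior, COR15A (0.0537) under quantile normalization, XTH19 (0.0532) after median centring, and COR15A and AT2G32160 (0.0530 each) with array weights. Sign changes occurred in genes that had not passed. Under quantile normalization SPL was at -0.0125, CLV3 at -0.0109 and GAPC2 at 0.0510, and with array weights FATA (FaTA) was at 6.71e-04. With 1 array left out, log2 changes ran from -0.0161 to 0.36 for OLEO3, -0.19 to 0.0585 for CHR17, -0.16 to 0.0544 for INO80, -0.0114 to 0.0732 for SPL, -0.0085 to 0.22 for IKU2, -0.0230 to 0.0445 for CLV3, -0.15 to 0.0082 for DFR, -0.0713 to 0.0684 for PYK10, -0.16 to 0.0350 for FATB, -0.11 to 0.0684 for FaTA, -0.0635 to 0.17 for BCAT4 and -0.0283 to 0.0201 for GAPC2; the cause was not tested.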

Other observations

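The test of symbol families and the test of dim rises and falls were chosen only after the results had been seen. Tau-class glutathione S-transferases (GSTU), enzymes that conjugate glutathione to toxins and stress metabolites, were lower in pkl-1 as a family (camera adjusted p = 0.0273 over 32 families), with an adjusted p of 0.515 under an estimated correlation. Changes were negative in 9 of the 11 members with a named probe set, with a median of -0.488 log2 units. The same 9 were negative under quantile normalization, which moved the median only to -0.492 and so tests little. Any members on unnamed probe sets are not covered. None of the 11 passed the test alone, GSTU26 coming closest at -0.94 ± 0.20 (limma adjusted p = 0.0607). No other family was shifted. A looser definition of families, tried first on the same data and so no independent evidence, gave GSTU alone among 34 (adjusted p = 0.0290).

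Of the changed genes with a symbol that the naming rule did not take, those with the largest changes were picked after their values were seen, and no common theme was tested. The largest rises were those of BGLU28, a beta-glucosidase gene, by 1.93 log2 units (adjusted p = 0.0127), TBL26 by 1.82 (adjusted p = 0.0497) and the cytochrome P450 gene CYP71B36 by 1.77 (adjusted p = 0.0284). The largest falls were -2.13 for PDF1.2b (adjusted p = 0.0162), a defensin gene close to PDF1.2 on a probe set that can cross-hybridise with relatives, -1.74 for CYP71B5 (adjusted p = 0.00396) and -1.60 for the subtilase gene SBTI1.1 (adjusted p = 0.00721).

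The genotype difference gave 540 changed probe sets (limma), and the highest of the other 9 splits of the arrays gave 0. At an unadjusted limma p under 0.05 the other split with the most had 2255 probe sets, against 3388. That split and the next, at 1779, set both replicates 1 against both replicates 3. The remaining splits gave 364 to 767, where 1137 are expected with no effect. The highest counts of the other splits thus go with the replicate numbers and do not measure chance. Each other split put both genotypes on each side, so that genotype differences widened its spread and its count of 0 decides nothing. With 10 splits, where 1 reached the real count, the share also cannot fall under 0.05. The 3' minus 5' signals of the GAPDH, actin and ubiquitin controls had ranges apart between genotypes for 0 of 3. For each control the pkl-1 range lay inside the wild-type range, for actin 0.448 to 0.534 against 0.308 to 0.842. This argues against a difference in RNA degradation between the genotypes larger than the spread of the wild-type arrays. With 3 arrays each, ranges overlap easily, so that a smaller difference cannot be excluded. Variants linked to pkl-1 may change genes near PKL: 3 of 81 named genes within 100 gene ranks of PKL were changed, an odds ratio of 1.86 (95% interval 0.373 to 5.70, Fisher's exact p = 0.228), too few to decide. Neighbouring changed genes may share a cause: 6 pairs of neighbouring named genes changed in the same direction, against a median of 3 in 10000 relabellings, at the upper limit of their central 95% (permutation p = 0.0612), which leaves it open. The effect of the genotype stays among the open explanations.

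The largest named rises began near background, which raised the question whether rises from there outnumber falls to there. Over all changed probe sets they did not: the mean of the lower genotype lay under 2.82 log2 units in 30 of 242 rises (12.4%) and 54 of 298 falls (18.1%), an odds ratio of 0.640 (Fisher's exact p = 0.0739). With a limit of 2.14 the odds ratio was 0.954 and with 5.09 it was 0.696 (Fisher's exact p = 0.0487). Of changes of at least 2-fold, 19 of 119 rises and 32 of 184 falls were of this kind, and of those of at least 8-fold, a size chosen after the data were seen, 6 of 10 rises and 0 of 6 falls. Less spread near background could let changes pass there more often in either direction. The median SD was 0.167 log2 units where the mean over all arrays lay under 2.82 and 0.198 elsewhere. Of such probe sets 47 of 7582 (0.620%) were changed, against 493 of 15164 elsewhere (3.25%). They passed less often in both directions, with 0.237% higher and 0.382% lower against 1.48% and 1.77%. These shares argue against more frequent passing for probe sets classed by their mean over all arrays. A change also moves a probe set's mean, and how many truly differ in each class is unknown, so that an effect of the spread itself is not settled. No biological explanation was tested.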
